A study of Mus musculus with 6 samples.

How the data were processed

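RNA was isolated from myocardium with column purification and on-column DNase digestion, and libraries were made with a stranded Illumina TruSeq kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19, kallisto 0.44.0 and the mouse genome build GRCm38. The deposited table holds raw counts per gene symbol for 6 libraries, read here as estimated counts that the authors made with kallisto, per the submitters' processing notes. That tool assigns reads to transcripts by probability and gives estimated and not observed counts. All values in the table were whole numbers. How transcripts were summed to symbols, how values were rounded, which transcript annotation was used and whether strand was used are not given in the sources used here. Because an estimate can divide the reads of near-identical transcripts by a single base, values of pseudogenes, multicopy genes and nuclear copies of mitochondrial genes are uncertain. Overlapping and antisense genes are uncertain because the use of strand is not given.

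The table listed 34945 symbols, of which 14853 had 0 counts in all 6 libraries. Each column was assigned to its mouse through the sample number and mouse code in the labels, and no sample column was left unused. Symbols were matched to GENCODE M21, an annotation of GRCm38, for coordinates and gene types: 34213 matched, 732 did not and 51 matched several genes. Of the matched symbols 21276 were protein coding and 12416 were pseudogenes, while 22 were lincRNAs, so long noncoding RNAs such as Xist are not analysed here. Whether libraries were duplicated was checked with a chi-square statistic per degree of freedom over genes for each pair within a genotype, which was 7.98 or more, far above sampling noise, and all 6 libraries were kept as separate mice. The labels carry no replicate number shared between the genotypes, and no batch, date or sex.

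Counts, rounded to whole numbers, were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr on genotype, which left 13485 genes with 99.96% of the counts, and libraries were scaled by TMM. Genotype was tested with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, two-sided, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene is called at an adjusted p below 0.05, and rose, fell or changed is written only of called genes. Log2 fold changes are knock-in minus wild-type, given ± SE where an error is printed, and CPM values are TMM-scaled counts-per-million, given as mean ± SD of 3 mice. The biological coefficient of variation was 8.35%. A fold against libraries that all had 0 counts is a lower bound against a floor of 3 counts per library. Floors and counting intervals cover counting error only. Principal components and correlations used log2-CPM with a prior count of 2.

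The design of the test, 34 gene lists, the rule for named genes and most of the other settings to be run were chosen before the data were examined. The 31 lists with at least 5 tested members, other than the strain and sex lists, were tested with camera (limma 3.58.1, two-sided, inter-gene correlation preset at 0.01) and adjusted over 31 lists. Of these, 5 were called as higher and 10 as lower, and none with a correlation estimated from the data, where the smallest adjusted p was 0.462. Through the adjustment most called lists share that value, so it does not rank them. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members of a list. Genes are named by this rule: Rrad; the 10 genes with the largest rise and the 10 with the largest fall among called genes whose CPM ranges do not overlap; up to 4 called members of each list by smallest p, or otherwise the 1 or 2 members with the smallest p; and Cacna1c, Cacnb2, Ryr2, Atp2a2, Pln, Slc8a1, Adrb1, Nppa, Nppb, Myh7 and Col1a1. Other list members are named as examples from the full tables, and genes named for any other reason are said to have been chosen after their values were seen. Some genes selected by the rule are not reported here.

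The pipeline was tested on simulated data with the fitted means, dispersions and library sizes of the 13485 genes and 200 changed genes. It recovered 22% of genes changed 1.25-fold, 66% at 1.5-fold, 78% at 2-fold and 88% at 4-fold, 7.3% of calls were false, and 0 genes were called when no gene was changed. Each share rests on 50 genes in a single draw, and genes were drawn independently, without effects shared within a library. With 200 changed genes, fewer genes passed than the 1215 called in the data, so the threshold on unadjusted p was stricter in the simulation. These shares therefore need not hold for the data, in which small differences can still be missed with 3 mice per genotype.

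The other settings were DESeq2 1.42.0, limma-voom, other scalings in edgeR (DESeq2 size factors, upper quartile, library size alone), no filter or a filter of 50 counts in 3 libraries, robust dispersions, an adjusted p of 0.1, each library left out in turn, sex-linked or mitochondrial genes left out, camera with an estimated correlation, and fry. Settings added after the data were seen left out copied, mitochondrial and strain-dependent genes together, or used a heat shock, atrial or erythroid score of each library as a covariate. Near-identical copies of mt-Nd3 and mt-Co2 were compared with them base by base in GRCm38 annotated transcripts.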

Results

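Left ventricular tissue from 6 mice was profiled by RNA sequencing, 3 wild-type mice and 3 mice carrying a knock-in allele of Rad named 4SA. Rad, the product of the gene Rrad, is a small GTP-binding protein of the RGK family that restrains voltage-gated calcium channels in heart muscle cells. The title of the series names its subject as the part that phosphorylation of Rad and calcium entry play in the cardiac fight-or-flight response. The single comparison in the design asks which ventricular transcripts differ between the genotypes. The labels give C57BL/6N as the strain of all 6 mice. The libraries held 24761124, 31827411 and 32669182 estimated counts in wild-type replicates 1 to 3, and 35259459, 36106441 and 39627397 in knock-in replicates 1 to 3, so that every knock-in library was deeper than every wild-type library. Transcripts of the mitochondrial genome took between 53.1% and 56.9% of the counts. Y-linked genes were detected in all 6 libraries.

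Knock-in ventricles carried lower levels of many immediate early genes, the transcription factors and regulators that cells induce within minutes of stimulation. Of 24 tested members 14 fell, with Egr3 at 8.63 ± 4.21 normalised counts-per-million (CPM) in wild-type and 0.576 ± 0.0304 CPM in knock-in (mean ± SD, n = 3 each). Also lower were 8 of 27 extracellular matrix genes, 6 of 14 inflammation genes (1 rose), 8 of 16 macrophage markers (2 rose) and the stress-associated transcripts Acta1 and Nppb. Myh7, the slow myosin heavy chain, rose 2.71-fold, but neither Myh7 (edgeR adjusted p = 0.123) nor Acta1 (0.171) nor Nppb (0.158) passed with robust dispersions. Of 30 genes of fatty acid oxidation 8 rose and 1 fell. No gene list was called when the correlation between genes was estimated from the data (smallest camera adjusted p = 0.462). The pacemaker channel gene Hcn4 and the T-type calcium channel genes Cacna1h and Cacna1g rose, although Cacna1g did not pass with robust dispersions (edgeR adjusted p = 0.11). Rrad and the cardiac L-type channel subunit genes Cacna1c and Cacnb2 did not pass the test. The accessory channel subunit gene Cacna2d1 rose from 123 ± 6.50 to 154 ± 8.81 CPM (edgeR adjusted p = 0.00773). The genotypes also differed in Nnt, Wdfy1, Entpd4 and mt-Nd3, genes known to differ between C57BL/6 substrains. The mt-Nd3 difference may be reads assigned to a near-identical pseudogene. Such values would arise if wild-type mice were of C57BL/6J type and knock-in mice of C57BL/6N type at these loci, although the labels give C57BL/6N for all. Substrain and the Rad allele follow the same split of the 6 mice, so the differences reported here cannot be assigned to either.

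Of 13485 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1215 (9.01%) passed an adjusted p of 0.05, 540 higher and 675 lower in knock-in. Most differences were small: 844 of the called genes changed by less than 1.5-fold, while 58 rose and 84 fell by more than 2-fold. The first principal component held 44.6% of the variance and separated the genotypes, and log2-CPM values correlated more closely within genotypes (r across genes 0.986 to 0.991) than between them (0.977 to 0.980). The CPM ranges of the groups did not overlap in 29.4% of tested genes, against 10% by chance. The number of calls depended on single libraries, falling to 338 without knock-in replicate 3, 485 without wild-type replicate 3, 672 without knock-in replicate 2, 746 without wild-type replicate 2 and 775 without wild-type replicate 1, and rising to 1378 without knock-in replicate 1. These fits have fewer mice. Of 124 called genes selected for naming, many by a small p or a large fold change, 61 were called in all 6 of them. Without knock-in replicate 3, 66 of these 124 were called, against 331 of all 1215 called genes. The split between directions depended on scaling, since library size alone gave 227 higher and 1177 lower genes, and upper-quartile factors 604 higher and 573 lower.

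**Figure D1:**
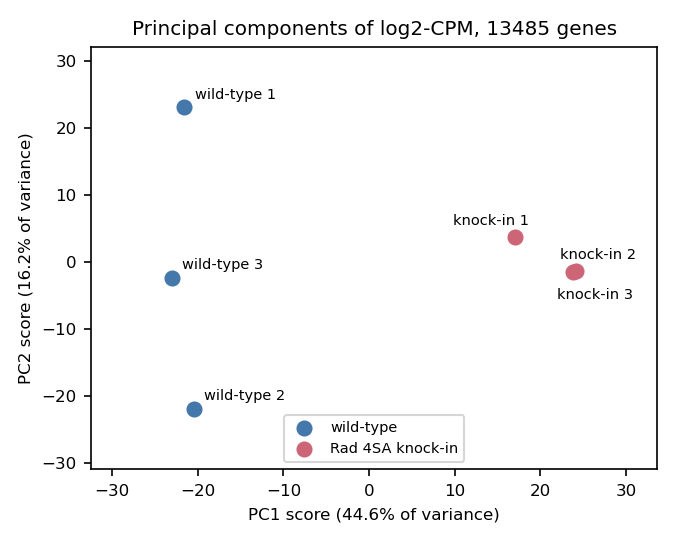
Scores of the 6 libraries on the first and second principal components of log2-CPM over 13485 genes, with the share of variance on each axis label and colours for genotype. The first component (44.6% of the variance) places the wild-type libraries on the left and the knock-in libraries on the right, and the second (16.2%) spreads the wild-type libraries.

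Rrad lies on chromosome 8 from 104628070 to 104631327 on the minus strand of GRCm38 and was read at 44.7, 30.0 and 32.2 CPM in wild-type replicates 1 to 3, and at 27.0, 56.8 and 42.3 CPM in knock-in replicates 1 to 3, from 890 to 1972 counts per library. The log2 fold change of 0.25 ± 0.23 (SE) was within the spread between mice (edgeR adjusted p = 0.554), and it was -0.03 without knock-in replicate 2. Total counts per gene do not distinguish the knock-in allele from the wild-type allele, so the level of Rrad does not check the genotype labels. Among 31 tested neighbours of Rrad, 1 rose (Pdp2, encoding a phosphatase of the pyruvate dehydrogenase complex, log2 fold change 0.36 ± 0.09, called in 2 of 6 fits that left out a library) and 30 did not pass the test, and none passed when adjusted over the list alone (camera adjusted p = 0.689). Within 10 Mb on either side of the gene, 6 of 142 tested genes were called, 4.23% against 9.06% elsewhere (Fisher's exact test, two-sided p = 0.0533).

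In the list of L-type calcium channel subunits and RGK proteins, 4 of 15 tested genes rose, none fell and 11 did not pass, and the count adjusted over the list alone was also 4. The members that rose were accessory or T-type subunits and not the pore of the cardiac L-type channel. Cacna1h, a T-type pore subunit, rose from 7.29 ± 1.35 to 12.5 ± 0.595 CPM (log2 fold change 0.77 ± 0.12, edgeR adjusted p = 0.00395), and Cacna2d1, an accessory subunit of high-voltage-activated channels, from 123 ± 6.50 to 154 ± 8.81 CPM (0.33 ± 0.06, edgeR adjusted p = 0.00773). Cacna2d2 rose by 1.17 ± 0.24 and the T-type subunit gene Cacna1g by 0.75 ± 0.16 on the log2 scale, but neither passed without wild-type replicate 3 (edgeR adjusted p = 0.067 and 0.087) or without knock-in replicate 3 (0.078 and 0.101). Neither passed with robust dispersions (0.0574 and 0.11), and Cacna1g did not pass without wild-type replicate 1 (0.0622). Cacna1c stood at 242 ± 7.14 CPM in wild-type and 260 ± 5.84 CPM in knock-in (0.10 ± 0.04, edgeR adjusted p = 0.175), and Cacnb2 at 54.9 ± 5.16 and 57.8 ± 3.26 CPM (0.07 ± 0.07, edgeR adjusted p = 0.568). The list was called as higher by camera (adjusted p = 0.0171), but not with an estimated correlation or without wild-type replicate 3 (camera adjusted p = 0.462 and 0.055). With an atrial or erythroid score as a covariate, chosen after the values were seen, it was not called (camera adjusted p = 0.0509 and 0.0505). With the atrial score Cacna1g and Cacna2d2 did not pass (edgeR adjusted p = 0.0776 and 0.0777), at log2 fold changes of 0.59 and 1.

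In the calcium handling list, 3 of 27 tested members rose, 1 fell and 23 did not pass. Adjusted over the list alone, 3 were higher and 2 lower, and camera did not call a net shift of the list (adjusted p = 0.973). Hrc, encoding the histidine-rich calcium-binding protein of the sarcoplasmic reticulum, rose by 0.18 ± 0.04 on the log2 scale. Camk2g rose by 0.33 ± 0.08 and Itpr1 by 0.23 ± 0.06, and S100a1 fell by 0.21 ± 0.05. Of 6 fits that left out a library, Hrc and Camk2g were called in 2, Itpr1 in 1 and S100a1 in 4. The ryanodine receptor Ryr2 (-0.03 ± 0.05), the calcium pump Atp2a2 (0.01 ± 0.04), its inhibitor Pln (0.12 ± 0.04) and the exchanger Slc8a1 (0.09 ± 0.06) did not pass the test.

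Of 33 tested genes of beta-adrenergic signalling, 4 rose, 2 fell and 27 did not pass. The counts adjusted over the list alone were 6 higher and 4 lower. The alpha-1 receptor genes Adra1b (13.7 ± 1.06 to 19.4 ± 1.11 CPM, log2 fold change 0.50 ± 0.07) and Adra1a (0.28 ± 0.06) rose, as did Akap5, an anchor of protein kinase A at the membrane (0.91 ± 0.15). Adra1a did not pass without wild-type replicate 1, wild-type replicate 2 or knock-in replicate 3 (edgeR adjusted p = 0.075, 0.0673 and 0.0997) or with library size alone (0.118). With a heat shock score, the mean log2-CPM of heat shock protein genes, as a covariate chosen after the values were seen, Adra1a, Adra1b and Akap5 did not pass (0.149, 0.0731 and 0.0953), at log2 fold changes of 0.29, 0.41 and 0.68. Grk2, a kinase that desensitises adrenergic receptors, fell from 34.6 ± 2.06 to 28.0 ± 1.12 CPM (edgeR adjusted p = 0.0154), and was called in 4 of 6 fits that left out a library. The beta-1 receptor gene Adrb1 was at 6.54 ± 0.370 CPM in wild-type and 6.92 ± 0.707 CPM in knock-in (edgeR adjusted p = 0.657). Camera did not call the list (adjusted p = 0.288), whereas fry, which asks whether members move one way on balance without comparison to other genes, did (adjusted p = 0.0407).

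Of 31 tested potassium, sodium and pacemaker channel and connexin genes, 7 rose, 4 fell and 20 did not pass. The counts were 10 higher and 8 lower adjusted over the list alone, and camera did not call a net shift of the list against other genes (adjusted p = 0.451). Among potassium channels, Kcnj5 (0.46 ± 0.05), Kcnh2 (0.42 ± 0.07) and Kcnj2 (0.76) rose on the log2 scale, and Kcna5 fell from 18.0 ± 3.02 to 9.04 ± 1.62 CPM (edgeR adjusted p = 0.00301). The ventricular connexin gene Gja1 rose (0.40) and the sodium channel subunit gene Scn4b fell (-0.60). Of 12 tested conduction system markers, 5 rose (Hcn4, Irx3, Slit2, Cacna1g and Cntn2), none fell and 7 did not pass. The counts were 7 higher and 1 lower (Tbx3) adjusted over the list alone. Log2 fold changes were above 0 for 9 of the 12 and below 0 for 3: Tbx3 (-0.30), Kcne1 (-0.52) and Gja5 (-0.12). Hcn4, the main pacemaker channel, rose from 6.06 ± 0.937 to 10.4 ± 1.07 CPM (edgeR adjusted p = 0.00508). The conduction list was called as higher (camera adjusted p = 0.0125), but not with an estimated correlation or without knock-in replicate 1 (camera adjusted p = 0.462 and 0.051). Nor was it called with fry (adjusted p = 0.102). With an atrial score as a covariate, chosen after the values were seen, it was also not called (camera adjusted p = 0.0509). Of 11 tested atrial markers, Tbx5 rose (0.45 ± 0.07) and 10 did not pass. The count was 1 adjusted over the list alone (camera adjusted p = 0.288). The mean log2-CPM of the atrial transcripts Myl7, Myl4 and Sln, set to a wild-type mean of 0, was 0.21, 2.14 and -2.34 in wild-type replicates 1 to 3, and 2.07, 1.25 and 1.38 in knock-in replicates 1 to 3.

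Sarcomere genes moved in both directions, with 2 of 22 tested members higher (Tpm1 and Tcap), 2 lower (Des and Actn2) and 18 not passing. Of 6 fits that left out a library, Tpm1 and Des were called in 2, Tcap in 1 and Actn2 in none. When adjusted over the list alone, 6 were higher and 4 lower. The median of that list was -0.04 while its mean was not below 0, and camera did not call a net shift (adjusted p = 0.973). Of 14 cardiomyocyte markers, Fabp3 rose (called in 3 of 6 such fits), Ckm fell and 12 did not pass. There were 5 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.973, median 0.01, mean -0.01). Of 16 tested genes of the hypertrophy and fetal programme, Myh7 rose, Meox1, Acta1, Ccn2 (called in 2 of 6 such fits) and Nppb fell and 11 did not pass. Adjusted over the list alone, 1 was higher and 6 lower. Myh7 rose from 82.0 ± 18.6 to 222 ± 88.0 CPM (log2 fold change 1.44 ± 0.26, edgeR adjusted p = 0.00993). Skeletal alpha-actin, Acta1, fell from 127 ± 23.1 to 59.6 ± 23.2 CPM (-1.09 ± 0.24, edgeR adjusted p = 0.0207), and the natriuretic peptide gene Nppb from 41.4 ± 8.67 to 26.4 ± 4.32 CPM (edgeR adjusted p = 0.0264). Nppa was at 53.9 ± 8.30 and 40.9 ± 10.3 CPM and did not pass (edgeR adjusted p = 0.151). The list was called as lower (camera adjusted p = 0.0125; adjusted p = 0.462 with an estimated correlation), and its members did not move together, since Myh7, a fetal isoform of the mouse ventricle, rose. With robust dispersions Myh7, Acta1 and Nppb no longer passed (edgeR adjusted p = 0.123, 0.171 and 0.158). With a heat shock score as a covariate, chosen after the values were seen, the log2 fold change of Myh7 was 0.68 and that of Acta1 -0.57, and neither passed (edgeR adjusted p = 0.11 and 0.242). Acta1 and Nppb also did not pass without wild-type replicate 1 (0.07 and 0.087), wild-type replicate 3 (0.053 and 0.104) or knock-in replicate 3 (0.088 and 0.123).

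**Figure D2:**
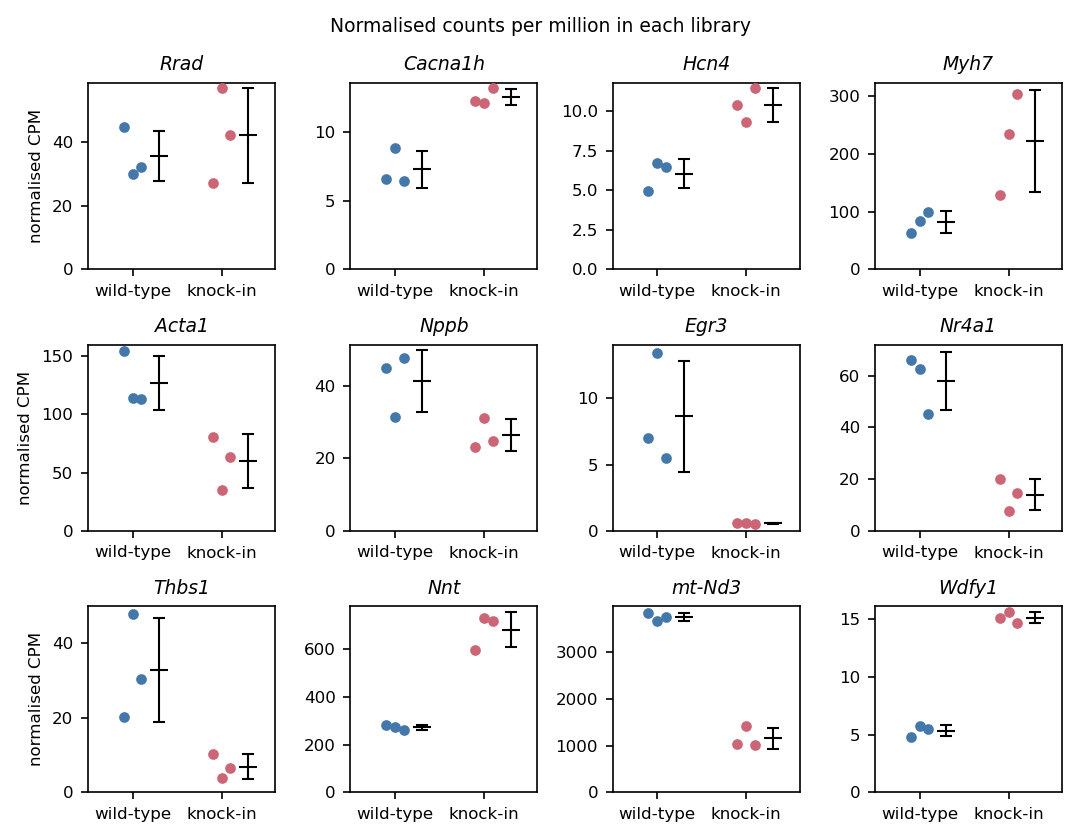
Normalised CPM of 12 genes in each library, wild-type in blue and knock-in in red, with black bars for the mean and 1 SD of 3 mice; each panel has its own axis from 0. Rrad overlaps between the genotypes, whereas Egr3 lies at 0.576 CPM in knock-in against 8.63 CPM in wild-type and Myh7 at 222 against 82.0 CPM.

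Of 27 tested genes of extracellular matrix and fibrosis, 8 fell, none rose and 19 did not pass. The count was 11 lower adjusted over the list alone. Thbs1, the matricellular protein thrombospondin-1, fell from 32.8 ± 13.9 to 6.90 ± 3.34 CPM (log2 fold change -2.27 ± 0.34, edgeR adjusted p = 0.00417; 0.085 with robust dispersions), Cilp by 1.32 ± 0.23 and Sparc by 0.30 ± 0.05 on the log2 scale. The fibrillar collagen gene Col1a1 did not pass (30.2 ± 4.00 and 27.3 ± 0.495 CPM, edgeR adjusted p = 0.316). The list was called as lower (camera adjusted p = 0.000969; adjusted p = 0.462 with an estimated correlation). Among 14 fibroblast markers, the microfibril genes Mfap5 and Mfap4 fell (called in 2 and 3 of 6 fits that left out a library) and 12 did not pass. Adjusted over the list alone, 1 was higher and 3 lower (camera adjusted p = 0.52). Of 10 tested epicardial and mesothelial markers, Wt1 fell from 6.06 ± 1.36 to 2.49 ± 0.548 CPM and 9 did not pass, with 1 lower adjusted over the list alone. All 10 had fold changes below 0, and the list was called (camera adjusted p = 0.0257; adjusted p = 0.573 with an estimated correlation). It was not called without wild-type replicate 2, wild-type replicate 3 or knock-in replicate 1 (camera adjusted p = 0.0857, 0.219 and 0.181), nor with library size alone (0.12), a filter of 50 counts in 3 libraries (0.0525) or fry (0.274). Of 14 endothelial markers, 5 fell, among them Esam (-0.38 ± 0.06), Eng (-0.22 ± 0.04) and Flt1 (-0.28 ± 0.07; called in 3 of 6 such fits), and 9 did not pass. The count was also 5 adjusted over the list alone (camera adjusted p = 0.0252; adjusted p = 0.462 with an estimated correlation). The endothelial call ended without knock-in replicate 1 or 3 (camera adjusted p = 0.135 and 0.0564). Of 12 smooth muscle and pericyte markers, Mylk fell (-0.30 ± 0.06, called in 4 of 6 such fits) and 11 did not pass, with 1 adjusted over the list alone (camera adjusted p = 0.307).

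Of 30 genes of fatty acid oxidation, 8 rose, 1 fell and 21 did not pass. There were 16 higher and 2 lower adjusted over the list alone. Ech1, a peroxisomal and mitochondrial isomerase of unsaturated fatty acids, rose from 468 ± 20.1 to 572 ± 18.6 CPM (log2 fold change 0.29 ± 0.05). Cpt1a, which commits fatty acids to mitochondrial import, rose from 30.6 ± 1.49 to 38.5 ± 1.59 CPM (0.33 ± 0.06). The related gene Cpt1b, at a wild-type mean of 325 CPM, did not pass (0.16 ± 0.05, edgeR adjusted p = 0.0954). Adjusted over the list alone, Cpt1b was higher (edgeR adjusted p = 0.0237). Ppara, a transcription factor for these genes, fell (-0.36). Camera called the list as higher (adjusted p = 0.000336; adjusted p = 0.462 with an estimated correlation). Of 21 glycolysis and glucose uptake genes, 6 fell, 1 rose and 14 did not pass, with the same counts adjusted over the list alone. Aldoa (-0.24 ± 0.05) and Eno3 (-0.20 ± 0.05; called in 2 of 6 fits that left out a library) were among those that fell, and Pfkfb1 rose from 9.88 ± 0.712 to 16.1 ± 0.545 CPM (edgeR adjusted p = 0.00082). The glycolysis list, lower on average, did not pass (camera adjusted p = 0.0724), but it did in 5 of 16 other settings chosen beforehand. Of 34 nuclear genes of oxidative phosphorylation, 4 fell, none rose and 30 did not pass. The count was also 4 adjusted over the list alone, and the median change was -0.06. Cox8b (-0.25 ± 0.04) and Atp5g1 (-0.28 ± 0.05) were among the 4, and the list was called as lower (camera adjusted p = 0.00696; adjusted p = 0.462 with an estimated correlation). Of 13 tested genes of the mitochondrial genome, 4 rose (mt-Nd5, mt-Nd4l, mt-Cytb and mt-Nd4, of which mt-Nd4l and mt-Cytb were called in 3 of 6 such fits), mt-Nd3 fell and 8 did not pass. Adjusted over the list alone, 4 were higher and 2 lower. The median of the mitochondrial list was 0.08 and its mean -0.03, and camera did not call it (adjusted p = 0.271). The fall of mt-Nd3, which lowers that mean, may be reads assigned to the near-identical pseudogene Gm28438. The summed CPM of both differed by -0.12 on the log2 scale, with 62.1% to 70.9% of it on Gm28438 in knock-in.

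Immediate early genes gave the lowest p of the 31 lists tested: 14 of 24 members fell, none rose and 10 did not pass. The count was 20 lower adjusted over the list alone (camera adjusted p = 1.15e-10). With an estimated correlation the camera adjusted p was 0.462 and the unadjusted camera p 0.033, the lowest of the lists tested. The zinc-finger factor genes Egr3 and Egr2 fell by 3.91 ± 0.36 and 4.22 ± 0.55 on the log2 scale (edgeR adjusted p = 0.000382 and 0.00207), and the orphan nuclear receptor gene Nr4a1 from 57.9 ± 11.2 to 14.1 ± 6.17 CPM (-2.04 ± 0.26, edgeR adjusted p = 0.0019). Fos, at a log2 fold change of -0.79, and Jun, at 0.17, did not pass (edgeR adjusted p = 0.17 and 0.55). The heat shock score was lower in knock-in replicates 2 and 3 than in the other 4 libraries. This score, the mean log2-CPM of the heat shock protein list set to a wild-type mean of 0, was 0.11, -0.06 and -0.05 in wild-type replicates 1 to 3, and 0.01, -1.29 and -1.12 in knock-in replicates 1 to 3. Of 16 heat shock genes, Hspa8, Bag3 and Hspb1 fell and 13 did not pass; each of the 3 was called in 1 of 6 fits that left out a library. The count was 8 lower adjusted over the list alone (camera adjusted p = 0.00179; adjusted p = 0.555 with an estimated correlation). With that score as a covariate, chosen after the values were seen, 243 genes were called.

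Of 22 tested genes of the integrated stress and unfolded protein responses, 6 fell, none rose and 16 did not pass, and 11 were lower adjusted over the list alone. Herpud1 (-0.47 ± 0.07), Xbp1 (-0.30 ± 0.06) and Manf (-0.35 ± 0.07), which act in the endoplasmic reticulum branch, were among those that fell. Manf was called in 4 of 6 fits that left out a library. The list was called as lower (camera adjusted p = 0.00093, and 0.462 with an estimated correlation). Circadian clock genes went both ways, with Bhlhe41, Hlf, Dbp and Nr1d1 higher (Hlf and Dbp called in 3 and 2 of 6 fits that left out a library), Per2 and Nfil3 lower and 15 of 21 not passing. When adjusted over the list alone, 4 were higher and 5 lower (camera adjusted p = 0.848). Per2 fell from 31.1 ± 2.49 to 16.8 ± 4.51 CPM (edgeR adjusted p = 0.009). Of 21 tested cell cycle genes, Cenpf rose (0.40 ± 0.10; called in 3 of 6 such fits) and 20 did not pass, with 1 adjusted over the list alone. Of the 21, 16 had fold changes below 0, and the list was not called (camera adjusted p = 0.0754), but was called as lower in 5 of 16 other settings chosen beforehand.

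Of 14 tested inflammation genes, 6 fell, 1 rose and 7 did not pass, with the same counts adjusted over the list alone. The chemokine genes Ccl2 (2.57 ± 0.913 to 0.620 ± 0.181 CPM) and Cxcl1 (2.57 ± 0.699 to 0.747 ± 0.0517 CPM) and the adhesion molecule gene Icam1 (15.3 ± 7.24 to 5.45 ± 0.304 CPM) were among those that fell, and Lcn2 rose (0.85). Icam1 was called in 4 of 6 fits that left out a library. The list was called as lower (camera adjusted p = 0.0125; adjusted p = 0.462 with an estimated correlation) but not without wild-type replicate 3 (camera adjusted p = 0.0619), with library size alone (0.0752), with a filter of 50 counts in 3 libraries (0.0603) or with fry (0.102). Among 27 interferon response genes, 6 rose, none fell and 21 did not pass, with 8 higher adjusted over the list alone. Psmb9, Iigp1 and Gbp7 rose by 0.82 ± 0.18, 0.57 ± 0.14 and 0.49 ± 0.13 on the log2 scale, and were called in 2, 1 and 1 of 6 fits that left out a library. The interferon list was called (camera adjusted p = 0.00101; adjusted p = 0.462 with an estimated correlation) but not without knock-in replicate 1 (camera adjusted p = 0.0845).

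Among blood and immune cell markers, macrophage and monocyte transcripts were more often lower than higher, with 8 of 16 falling, 2 rising and 6 not passing. The counts were 9 lower and 3 higher adjusted over the list alone. Lyz2 fell from 60.9 ± 1.15 to 42.6 ± 3.43 CPM (log2 fold change -0.51 ± 0.06, edgeR adjusted p = 0.00129). The complement genes C1qb and C1qc fell by 0.49 ± 0.09 and 0.49 ± 0.08 on the log2 scale, whereas the chemokine receptor genes Ccr2 (1.31) and Cx3cr1 (1.73) rose. The macrophage list was called as lower (camera adjusted p = 0.00179; adjusted p = 0.462 with an estimated correlation). Of 8 tested lymphocyte and neutrophil markers, 3 rose, among them the B cell transcripts Igkc and Ighm (Ighm called in 3 of 6 fits that left out a library), none fell and 5 did not pass, with 5 higher adjusted over the list alone. Igkc went from 0.491 ± 0.167 to 4.11 ± 1.85 CPM (edgeR adjusted p = 0.00229). The list was called (camera adjusted p = 0.0125; adjusted p = 0.462 with an estimated correlation) but not without knock-in replicate 1 or 3 (camera adjusted p = 0.111 and 0.0665). All 8 tested erythroid markers had fold changes above 0 (median 1.29), and none passed, also adjusted over the list alone. The erythroid list was not called (camera adjusted p = 0.118), but was called as higher in 3 of 16 other settings chosen beforehand. Their mean log2-CPM relative to wild-type was 1.12, -0.87 and -0.25 in wild-type replicates 1 to 3 and 2.28, -0.64 and 1.24 in knock-in replicates 1 to 3, so that the spread within each genotype exceeded the difference.

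**Figure D3:**
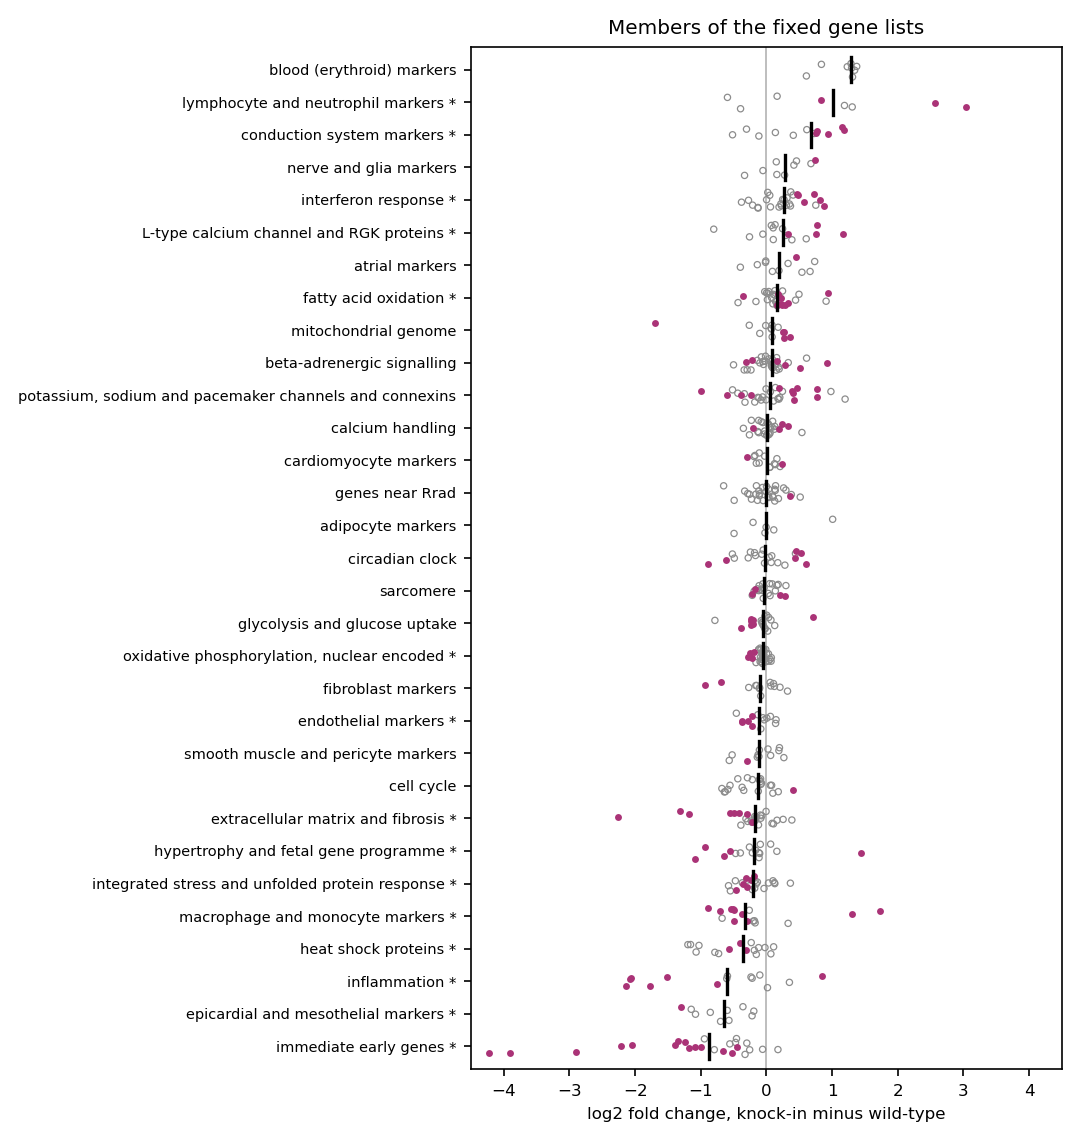
Log2 fold change (knock-in minus wild-type) of every tested member of the 31 gene lists tested as sets, with filled points for genes past an edgeR adjusted p of 0.05, open points for the rest and a black bar at each median; vertical scatter within a line has no meaning. An asterisk marks the 15 lists called by camera with a preset correlation of 0.01, 10 lower and 5 higher in knock-in, none of which was called with an estimated correlation.

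None of the remaining lists was called as a set in the main test. None of 6 tested adipocyte markers passed over all genes or adjusted over the list alone, with Pparg at -0.49 ± 0.18 and Scd1 at -0.20 ± 0.09 (camera adjusted p = 0.954; median -0.01, mean 0.07). Of 9 nerve and glia markers, Dbh, the enzyme that makes noradrenaline, rose from 1.92 ± 0.245 to 3.19 ± 0.286 CPM and 8 did not pass. Dbh was called in 4 of 6 fits that left out a library. The count was 1 adjusted over the list alone (camera adjusted p = 0.0815, median 0.28). The nerve and glia list was called as higher in 3 of 16 other settings chosen beforehand. Skeletal muscle and sex-linked genes had fewer than 5 tested members and were not tested as sets. In the skeletal muscle list Neb fell (5.87 ± 0.452 to 3.17 ± 0.736 CPM) and 3 genes did not pass, and in the sex-linked list the Y-linked gene Eif2s3y fell (33.9 ± 0.425 to 26.2 ± 3.47 CPM; called in 2 of 6 fits that left out a library) and 3 did not pass. The counts of both were the same adjusted over the list alone.

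Some of the smallest p values belonged to genes known to differ between C57BL/6 substrains. Nnt, a mitochondrial proton-pumping transhydrogenase whose gene is truncated in C57BL/6J, is annotated on the minus strand of chromosome 13 as a pair of overlapping gene models, the longer from 119335448 to 119408997 of GRCm38, and rose 2.50-fold, from a mean of 272 CPM to 680 ± 73.8 CPM (log2 fold change 1.32 ± 0.07, edgeR adjusted p = 2.02e-05). Wdfy1 rose from 5.35 ± 0.497 to 15.1 ± 0.456 CPM (edgeR adjusted p = 2.02e-05), and Entpd4 fell from 65.0 ± 5.54 to 31.5 ± 1.15 CPM (edgeR adjusted p = 3.17e-05). Those were the called members of the strain-dependent list, in which 4 of 7 tested genes did not pass, with 2 higher and 2 lower adjusted over the list alone. Its median was -0.19 and its mean 0.07. Entpd4b, a near neighbour of Entpd4 noticed after its values were seen, fell by 1.01 ± 0.07. The mitochondrial gene mt-Nd3, at 9459 to 9806 of the mitochondrial chromosome, fell from 3753 ± 89.6 to 1155 ± 222 CPM (-1.70 ± 0.11, edgeR adjusted p = 3.17e-05). The summed CPM of mt-Nd3 and the pseudogene Gm28438, described below, differed by only -0.12 on the log2 scale. This fall therefore need not be lower expression of mt-Nd3.

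Gm28438, an unprocessed pseudogene on chromosome 1 from 24612775 to 24613119 of GRCm38, had 0 counts in every wild-type library and between 80134 and 84768 in the knock-in libraries. It was at least 23237-fold higher in knock-in against a floor of 3 counts per library. Its annotated sequence matched that of mt-Nd3 over 345 bases except for T3C, with the mt-Nd3 base first and positions counted from 1 at its first base, which is position 9461 of the mitochondrial chromosome. Over those 345 bases, that base alone can divide reads between mt-Nd3 and Gm28438; the annotated mt-Nd3 is 348 bases long. Some other genes at the extremes were read in a single genotype or nearly so. Rps13-ps2, Gm5859 and Gm21451 had 0 counts in all knock-in libraries and were at least 16.5-fold, 13.7-fold and 9.81-fold lower. Gm6851 had 0 counts in all wild-type libraries and was at least 7.41-fold higher. Gm10600 and Gm13301 had 3 counts each in the knock-in libraries together, at wild-type to knock-in ratios of 71.0 (95% counting interval 23.9 to 348) and 58.1 (19.5 to 285). Mpc1-ps rose (0.0512 ± 0.0887 to 5.08 ± 0.569 CPM). Gm16867, Gm15446 and Cbx3-ps6 fell, and Gm14288 and Rps13-ps1 rose from up to 52 and 155 counts in a wild-type library. Of 6 fits that left out a library, Cbx3-ps6 and Rps13-ps1 were called in 2 and Gm14288 in 4, and Gm6851 was called in the 4 that tested it. Whether reads of these other genes are shared with similar copies was not tested. Besides Egr2, Egr3 and Igkc, the extremes included the lymphoid genes Igha (5.07 ± 0.95), Pax5 (2.48 ± 0.51) and Ms4a4b (2.37 ± 0.56), all of which rose from a wild-type mean of 0.126 CPM or less; they were called in 4, 3 and 3 of 6 such fits.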

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

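The runs with a heat shock, atrial or erythroid score as a covariate and the run without copied, mitochondrial and strain-dependent genes were chosen only after the results were seen, and the others before the data were examined. The 1215 calls moved by less than 1.5 times with DESeq2 (1063, of which 961 were shared) and limma-voom (1252, 1170 shared). The same held for DESeq2 size factors (1211), upper-quartile factors (1177), library size alone (1404), no filter on low counts (1591), a filter of 50 counts in 3 libraries (1229), and robust dispersions (1326). It also held with sex-linked genes left out (1215), mitochondrial genes left out (1207), copied, mitochondrial and strain-dependent genes left out (1160) and the erythroid covariate (981). Leaving out each library gave 338 to 1378 calls, 136 to 601 higher and 202 to 777 lower. These fits have fewer mice. Without knock-in replicate 3, wild-type replicate 3, knock-in replicate 2, wild-type replicate 2 and wild-type replicate 1 the count was 338, 485, 672, 746 and 775. Of 124 genes selected for naming and called over all genes, 66 were called without knock-in replicate 3 and 117 without knock-in replicate 1, and 61 in all 6 such fits. The heat shock covariate, which itself follows genotype (r = -0.70 across the 6 libraries), left 243 calls (107 higher, 136 lower; 204 shared), and the atrial covariate 451 (184 higher, 267 lower; 426 shared). An adjusted p of 0.1 gave 2006 (899 higher, 1107 lower) by its own construction. Library size alone gave 227 higher and 1177 lower, or 16.2% higher against 44.4%, and shifted the median gene by -0.08 on the log2 scale. Upper-quartile factors gave 604 higher and 573 lower (51.3% higher), with a shift of 0.02. A sex covariate was not run, because Y-linked genes were detected in all 6 libraries.

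Of the called lists, 5 higher and 10 lower, 0 and 0 were called with an estimated correlation. Over all lists fry called 2 higher and 5 lower: of the 5 higher lists only that of L-type channels and RGK proteins, with beta-adrenergic signalling in addition, and 5 of the 10 lower. The atrial covariate left 3 higher, and leaving out a library gave 2 to 7 higher and 8 to 11 lower, with 2 higher without knock-in replicate 1. Matrix, fatty acid oxidation, oxidative phosphorylation, stress response, heat shock, hypertrophy, macrophage and immediate early gene lists were called in all 6 fits that left out a library. Of these, the matrix, fatty acid oxidation, heat shock and hypertrophy lists were not called with fry (adjusted p = 0.102, 0.0645, 0.186 and 0.0645). Lists not called in the main test were called in some of the 16 settings chosen beforehand: cell cycle (lower) and glycolysis (lower) in 5, nerve and glia (higher) and erythroid (higher) in 3, and atrial (higher) and beta-adrenergic (higher) in 1. The list of the mitochondrial genome (higher) was called in 1 of 15. Among the called genes, robust dispersions ended the calls of Myh7, Acta1, Nppb and Thbs1 (edgeR adjusted p = 0.123, 0.171, 0.158 and 0.085), and so did the heat shock covariate (0.11, 0.242, 0.072 and 0.061). With that covariate the log2 fold change of Myh7 went from 1.44 to 0.68, of Acta1 from -1.09 to -0.57 and of Thbs1 from -2.27 to -1.78, while that of Nppb went from -0.65 to -0.84.

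Directions turned only for results that had not passed the test, and the cause was not tested. Rrad had a log2 fold change of -0.35 with the heat shock covariate and -0.03 to 0.48 when a library was left out, below 0 without knock-in replicate 2. With the heat shock covariate Adrb1 was at -0.05, Cacnb2 at -0.03 and Ryr2 at 0.04, and with library size alone Atp2a2 was at -0.07 and Cacnb2 at -0.01. Atp2a2 was at -0.02 with the atrial and 0 (just below) with the erythroid covariate. When a library was left out Atp2a2 ranged from -0.02 (without wild-type replicate 3) to 0.03, and Ryr2 from -0.06 to 0.01 (without knock-in replicate 2). Among lists, the camera adjusted p of the reversed direction was 0.615, 0.859, 0.906 and 0.913 for calcium handling (library size alone, no filter, heat shock and atrial covariates). It was 0.664, 0.913, 0.862 and 0.901 for cardiomyocyte markers (library size alone, no filter, atrial and erythroid covariates). For sarcomere genes it was 0.929, 0.992 and 0.705 (upper quartile, strict filter, atrial covariate) and 0.964 with fry, for adipocyte markers 0.834 (heat shock covariate) and for atrial markers 0.808 (atrial covariate). Leaving out a library gave adjusted p from 0.86 to 0.991 for calcium handling, 0.77 to 0.989 for cardiomyocyte, 0.528 to 0.969 for sarcomere, 0.327 to 0.989 for adipocyte, 0.475 to 0.989 for circadian and 0.216 to 0.932 for fibroblast lists. In each of these at least 1 library turned the sign. Across the other list and gene settings, 491 list values kept direction and side of the threshold, 22 newly passed and 48 no longer passed, and for the genes selected for naming 2309, 11 and 386.

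With 3 mice per genotype, 22% of genes changed 1.25-fold were recovered in a simulation of 200 changed genes. Its threshold on unadjusted p was stricter than that of the data, so this share need not hold for the data. Small changes among the genes that did not pass remain undetermined at this depth.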

Other observations

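All tests in this part were chosen after the result they bear on was seen, except the fits that left out a library and the count over splits of the libraries. The further glucocorticoid-induced genes were chosen before their own values were seen, but after the fall of the genes that prompted their test. Some genes outside the lists were chosen after their values were seen. Bdh1, which oxidises the ketone body beta-hydroxybutyrate, fell from 75.5 ± 5.21 to 28.3 ± 3.52 CPM in knock-in (mean ± SD, n = 3 each; edgeR adjusted p = 2.58e-05). The insulin receptor substrate gene Irs2 fell from 27.7 ± 3.75 to 7.24 ± 3.58 CPM and the glutamine synthetase gene Glul from 337 ± 11.5 to 219 ± 4.40 CPM (edgeR adjusted p = 0.00262 and 6.39e-05). Ptgds, a prostaglandin synthase, fell 2.67-fold and Cpxm2, a carboxypeptidase-like protein, 3.26-fold. All 5 kept their calls when any single library was left out.

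Zbtb16, Sgk1, Errfi1, Map3k6 and the metallothionein genes Mt1 and Mt2, which glucocorticoids induce in many tissues, also fell, with log2 fold changes between -0.75 for Sgk1 and -1.53 for Mt2, chosen after their values were seen. A candidate explanation is lower glucocorticoid signalling in the knock-in samples. In a set of 9 other glucocorticoid-induced genes, 4 fell (Fkbp5, Ddit4, Klf15 and Mertk), 1 rose (Galnt15) and 4 did not pass (edgeR adjusted p over all genes), with a median log2 fold change of -0.26. Camera gave p = 0.065 for the set, and p = 0.354 with an estimated correlation, so the test leaves the hypothesis open.

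The first pattern is a substrain signature that follows genotype: Nnt, Wdfy1, Entpd4, Entpd4b, mt-Nd3 and Gm28438 separated all 3 knock-in from all 3 wild-type libraries. Reads of a single mitochondrial transcript may be divided between mt-Nd3 and Gm28438 by the base T3C, because their summed CPM differed by only -0.12 ± 0.08 (SE) on the log2 scale while each moved by more than 1 in opposite directions. Gm28438 took 0% of the sum in wild-type and 62.1% to 70.9% in knock-in. The Nnt difference of 1.32, higher in the group whose reads fall on the C-bearing copy, is consistent with knock-in mice of C57BL/6N type and wild-type mice of C57BL/6J type at these loci, although the labels give C57BL/6N for all. Leaving out copied, mitochondrial and strain-dependent genes left 1160 calls, but substrain, the Rad allele and any other difference between the groups of mice follow the same split, so their parts in those calls cannot be told apart.

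The 10 splits of the libraries into 3 against 3 are too few for a share below 0.05. The real split, the 1 with as many calls, gave 1215 and the highest other 0 with edgeR (843 at an unadjusted p below 0.05, and 1 with limma-voom). Every other split mixes the genotypes, so a difference between genotypes widens the spread within its groups. Low counts in those splits therefore follow from the design, and no conclusion is drawn from them.

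The second pattern is the lower level of immediate early genes, which tissue handling can induce. A handling difference that also moves heat shock genes was tested with the heat shock score as a covariate. The genotype term of the immediate early score went from -1.15 (95% interval -1.68 to -0.62) to -0.89 (-1.56 to -0.21), and so kept most of its size. The heat shock score varied little in wild-type and mainly separated knock-in replicate 1 from knock-in replicates 2 and 3. The adjusted term therefore rests largely on knock-in replicate 1, and the score need not capture all effects of handling, so the test cannot exclude this cause. Knock-in replicate 1, with a heat shock score of 0.01, close to wild-type, had an immediate early score of -0.89, against -1.37 and -1.19 in knock-in replicates 2 and 3 and -0.25 to 0.19 in wild-type. Handling, with or without an effect on heat shock genes, substrain and the Rad allele were not told apart and stay open.

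The third pattern is the higher level of most conduction system markers, which atrial or atrioventricular tissue in a ventricular sample could raise. Tbx3, Kcne1 and Gja5 had log2 fold changes below 0 (-0.30, -0.52 and -0.12). With the atrial score of Myl7, Myl4 and Sln as a covariate, the genotype term of the conduction score went from 0.48 (95% interval 0.02 to 0.95) to 0.36 (-0.20 to 0.91): most of its size stayed and the interval widened to include 0. Wild-type replicate 2, with an atrial score of 2.14, had a conduction score of 0.27, against 0.29 to 0.61 in knock-in libraries with atrial scores of 1.25 to 2.07. Differences in the tissue taken and a change in ventricular or conduction cells cannot be told apart with 6 libraries.

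Gm28661, an unprocessed pseudogene identical to mt-Co2 over 681 bases, rose from 6089 ± 2091 to 18693 ± 3106 CPM, chosen after its values were seen, while mt-Co2 itself did not pass (log2 fold change -0.26, edgeR adjusted p = 0.096). Reads that lie within those 681 bases cannot be assigned to either gene, and the annotated mt-Co2 is 684 bases long.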
